A study of Oryctolagus cuniculus with 10 samples.

How the data were processed

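RNA was measured in 10 libraries of rabbit infrapatellar fat pad stem cells, 5 of expanded cells and 5 of pellets after 21 days in chondrogenic medium, 1 for each substrate. Per the labels' protocols, total RNA was isolated with Trizol and an RNeasy kit, and libraries were made with the KAPA mRNA HyperPrep kit. Per the submitters' processing notes, the tools were Subread and featureCounts and the genome build was OryCun2.0; their versions, the annotation release and the strand setting are not given in the sources used here. The deposited table holds log2 values for 29587 genes, with 1 column per library. The values themselves show how the authors scaled them: each deposited log2 value equals log2(RPKM + 1) with 0.0001 added. The scale was read from low genes, whose values become whole multiples of a single-read step only after this transformation is undone. Whole reads were recovered in this way for all 21536 genes above 0 in any library, with a deviation from a whole number of at most 0.02. The smallest whole numbers in the right proportions were taken, so reads that share a common factor are understated. A gene with reads in 1 library only always gets 1 read, so the recovery of such genes was fixed in advance. Across libraries, the totals of the recovered reads were proportional to the totals that the single-read steps imply, with ratios of 0.99992 to 1.0001 relative to their mean, so the RPKM were scaled in proportion to the reads counted in genes; gene lengths were not used, so the absolute divisor was not checked. The other 8051 genes had no reads in any library.

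The libraries held 18185672 (plastic), 14019466 (ASC), 15728937 (DF), 19826154 (SDSC) and 18449539 (USC) counted reads in cells, and 17591291, 15009094, 19389379, 19180825 and 19154875 in pellets, in the same order. At a mean of 5 to 20 RPKM a gene had a median of 353 reads per library, a coefficient of variation of 5.32% from counting alone. Such errors cover counting only, not differences between cultures. The 100 most abundant genes held from 28.7% to 36.2% of the RPKM in cells and from 24.6% to 27.9% in pellets.

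Groups were taken from the labels, with stage and substrate both read from the sample titles. All tests ran on log2(RPKM + 1), a pseudocount of 1 RPKM, which understates the change of low genes. Genes with a mean of at least 1 RPKM over the 10 libraries were tested, 12244 in all. Moderated tests were made with limma 3.58.1 in R 4.3.3, with a variance prior that follows expression level, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Pellets were compared with cells in a model with stage and substrate. The design text says that cells from each substrate went into pellets, which is where the pairing comes from. Deviations of cells from their stage mean correlated across genes with those of their own pellets at 0.085 (plastic), -0.088 (ASC), 0.144 (DF), 0.239 (SDSC) and -0.030 (USC), so the data show little of the pairing. dECM was compared with plastic in a model with a mean for each stage and class, fitted to all 10 libraries with 1 shared spread. A stage has 4 dECM libraries and 1 plastic library. The single plastic library leaves no residual, so the spread comes from the dECM libraries of both stages alone. Plastic was assumed to vary like them. USC dECM was compared with the other dECMs in a model with stage and 3 classes. p-values therefore measure the spread between substrates, not between replicate cultures, animals or library preparations. Single libraries were compared by counts of genes that differ by at least 1 on the log2 scale, with no test. Root-mean-square differences, principal components and simulated counting error (Poisson reads around the stage mean) were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures with matplotlib 3.10.9.

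The limma steps were tested on simulated data in which 50 genes each were changed 1.5, 2, 4 and 8-fold among the 12244. For pellets against cells, 40%, 88%, 98% and 100% were recovered. For dECM against plastic in cells the shares were 0%, 32%, 92% and 88%, and in pellets 8%, 22%, 88% and 90%. For USC against other dECMs they were 24%, 66%, 94% and 96%, with each change put into both USC libraries alike.

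The comparisons, the alternatives and the rule for naming genes were fixed before the data were examined. That rule took, among genes with a symbol, those with the largest rise and fall past the threshold (moving the same way in all 5 substrates for pellets against cells, with a minimum mean RPKM), together with a set of cartilage genes. The only table of gene names used here, for assembly mOryCun1.1, lists 38822 genes without Ensembl identifiers, and 0 of the identifiers matched. No gene could therefore be named, the 34 gene lists fixed in advance were not tested, and the same ranking without the symbol condition gave 2 identifiers that rose and 2 that fell in pellets. Genes were not placed on chromosomes, because no annotation of the build OryCun2.0 was used here. Alternatives were another pseudocount, other filters, 3 other scalings, a variance prior without the trend, a minimum change, the model without the substrate term, fits within a stage, and leaving out the libraries of each substrate in turn. Alternatives added after seeing the data were limma-voom on the recovered reads, the substrate as a block in the test of pellets minus cells, and leaving out the SDSC dECM pellet library.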

Results

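Stem cells from the infrapatellar fat pad, the cushion of fat below the kneecap, were taken from New Zealand White rabbits. They were expanded either on tissue culture plastic or on decellularized extracellular matrix (dECM), the matrix that remains after the cells that laid it down have been removed. The dECMs were deposited by human cells of 4 kinds, abbreviated in the sample titles as ASC, DF, SDSC and USC, of which the series title spells out urine stem cells (USC). Expanded cells were sequenced directly, and cells from each substrate were also sequenced after 21 days as pellets in chondrogenic medium, which drives them towards cartilage. The series comprised 10 mRNA libraries, 1 for each of the 5 substrates at each of the 2 stages. No substrate was replicated within a stage. Reads assigned to genes numbered from 14019466 in the ASC dECM cell library to 19826154 in the SDSC dECM cell library. A gene with a mean of 1 to 2 RPKM (reads relative to gene length and library size) had a median of 35 reads per library, for which counting error alone gives a 95% Poisson interval of 24.4 to 48.7. The deposited table lists rabbit genes by Ensembl identifier and does not pair them with names, so genes are reported as groups, with a few identifiers.

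Stage separated the libraries more than substrate did. On the first principal component of log2(RPKM + 1), which held 70.5% of the variance, the 5 cell libraries scored between -52.9 and -39.9 and the 5 pellet libraries between 35.5 and 53.4. Substrates were spread along the second component (12.01% of the variance) in the cells, from -27.8 on ASC dECM and -23.3 on DF dECM through -10.1 on USC dECM and 20.7 on SDSC dECM to 45.1 on plastic. The pellets lay between -7.19 and 8.73 on that component.

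**Figure D1:**
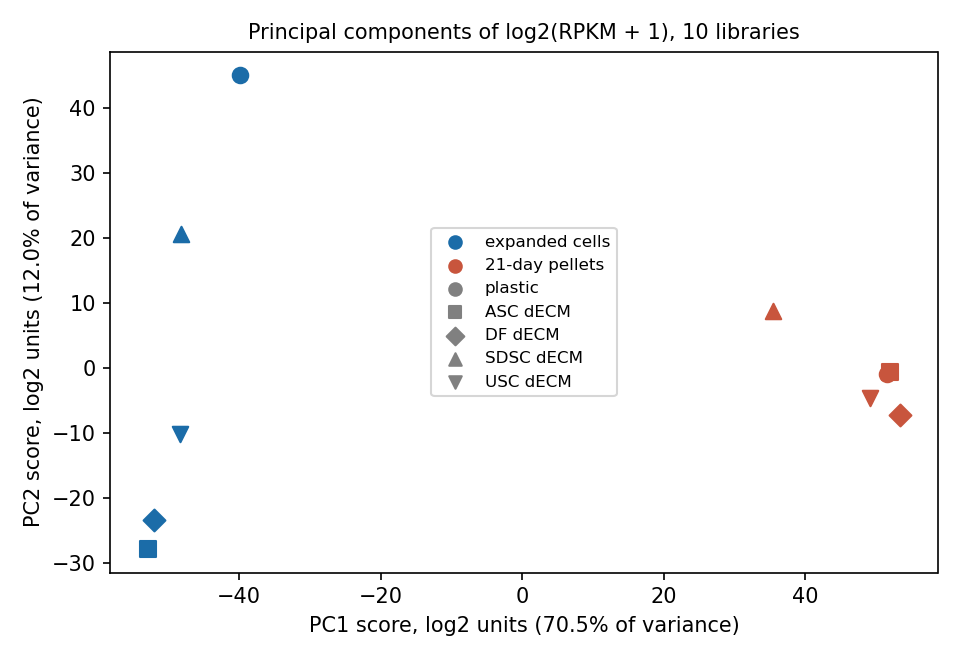
Scores of the 10 libraries on the first and second principal components of log2(RPKM + 1), in log2 units, with colour for the stage and marker shape for the substrate. Pellets lie at 35.5 or above on the first component, and the plastic cell library lies highest on the second, at 45.1.

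Pellets were compared with the cells they were made from to ask what changes during chondrogenic culture. Of 12244 genes tested, 4626 were higher in pellets and 2283 were lower. The genes called higher had a median log2 change of 0.67 and those called lower a median of -0.75. A change of at least 1 on the log2 scale was found in 1107 genes called higher and in 752 called lower, and a change of at least 4 in 39 and 20 genes. ENSOCUG00000017958 rose the most, from 5.99 ± 8.66 RPKM in cells to 721 ± 695 RPKM in pellets (SD, n = 5 each), a log2 change of 7.24 with an SE of 0.44 (limma, adjusted p = 3.57e-05). Among the pellets it ranged from 162 RPKM after plastic to 1933 RPKM after DF dECM. ENSOCUG00000016101 rose from 1.16 ± 0.504 to 263 ± 130 RPKM (SD, n = 5 each), a log2 change of 6.83 with an SE of 0.14 (limma, adjusted p = 1.51e-06). ENSOCUG00000022646 fell from 778 ± 590 to 0.878 ± 1.17 RPKM (SD, n = 5 each), a log2 change of -8.44 with an SE of 0.45 (limma, adjusted p = 1.89e-05), and had no reads in the pellets after plastic and after USC dECM. ENSOCUG00000008632 fell from 1025 ± 752 to 1.67 ± 1.31 RPKM (SD, n = 5 each), a log2 change of -8.37 with an SE of 0.39 (limma, adjusted p = 1.66e-05). In the cells, both of the falling genes were lower on plastic (194 and 446 RPKM) and on SDSC dECM (219 and 260 RPKM) than on ASC dECM (1397 and 1918 RPKM), with 1 library behind each value.

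**Figure D2:**
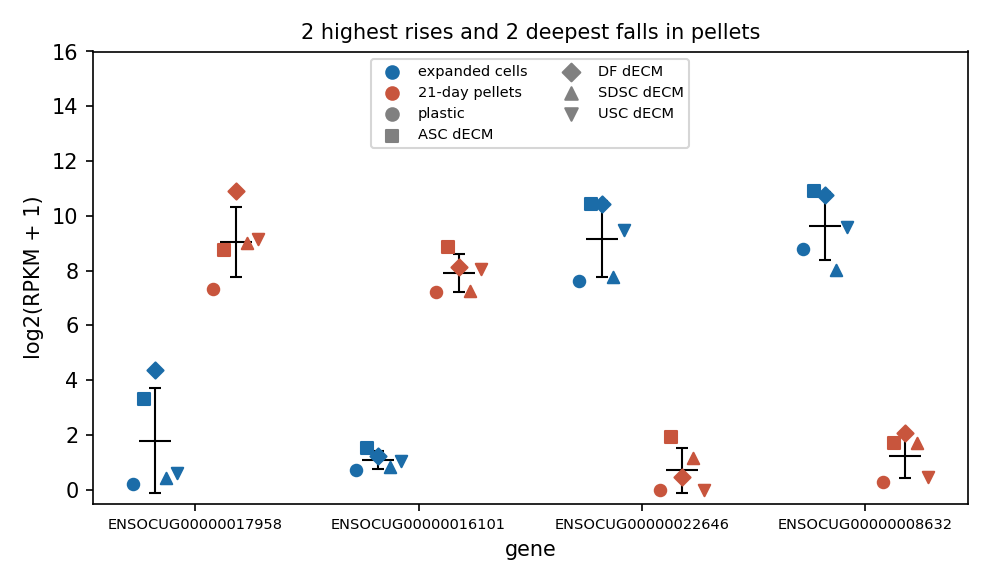
log2(RPKM + 1) of the genes with the 2 largest rises and the 2 largest falls in pellets, with 1 point per library, colour for the stage, marker shape for the substrate, and a horizontal bar and whiskers for the mean and SD over the 5 libraries of a stage. Every pellet point lies above every cell point for ENSOCUG00000017958 and ENSOCUG00000016101, and below every cell point for the other two.

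The direction of the change was shared across substrates in many genes. Of all 12244 tested genes, called or not, 7061 (57.7%) moved the same way in all 5 substrates, against 6.25% for genes whose direction is random and independent in each substrate. Among the 6909 called genes the number was 6395, which the test itself favours because it calls genes that change alike across substrates. A scaling offset between the stages that all 5 pairs share would also move directions alike. The 57.7% was not recomputed with another scaling. The change was tested with limma across the 5 substrates, each pellet library set against the cell library of its own substrate, so the error is the spread of the change between substrates and not between repeated cultures. The balance of higher and lower genes depended on how the libraries were scaled. The median change of all tested genes was 0.18 with the RPKM as deposited, and genes higher in pellets made up 67.0% of the calls. Median-of-ratios scaling moved that median by -0.17 and gave 3350 higher and 3169 lower genes (51.4% higher). Quantile normalization gave 3365 and 3212 genes (51.2% higher). Scaling to the same RPKM total gave 5326 and 2013 (72.6% higher).

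Growth on dECM was compared with growth on plastic, first in the expanded cells, to ask what the matrix changes before chondrogenic culture starts. In cells, 54 genes were higher on the 4 dECMs than on plastic and 167 genes were lower (limma, adjusted p under 0.05). The median log2 difference was 1.89 for the genes called higher on dECM and -1.61 for those called lower. A difference of at least 2 on the log2 scale was found in 23 of the genes higher on dECM and in 39 of those lower. The 12244 tested genes together had a median difference of -0.04. The comparison sets 4 libraries on different dECMs against 1 plastic library, which was assumed to vary like the others. It depended on single substrates: no gene was called without the ASC libraries or without the USC libraries, and none when the cell libraries were fitted alone, while 566 higher and 697 lower genes were called without the SDSC libraries, and 24 and 31 with a pseudocount of 0.1 RPKM.

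In pellets, no gene was called between the 4 dECMs and plastic by limma, and the smallest adjusted p was 0.639. At an unadjusted p under 0.05 there were 898 genes (7.33% of those tested), against 2022 (16.5%) in cells, and limma-voom on the recovered reads also called 0. Without the filter on low genes, 104 genes were called. The dECM minus plastic difference was tested for a change between cells and pellets in a model that takes the libraries as independent, and 1 gene passed, with 1370 genes at an unadjusted p under 0.05. This gene, ENSOCUG00000011482, is named because it is the only call and was chosen after its values were seen. In cells it was lower on dECM (4.34 ± 0.959 RPKM, SD, n = 4) than on plastic (43.3 RPKM), and in pellets it stood at 610 ± 161 RPKM after dECM (SD, n = 4) and 295 RPKM after plastic. The difference between those differences was 4.08 on the log2 scale with an SE of 0.42 (limma, adjusted p = 0.0362), while its difference in pellets alone was not called (limma, adjusted p = 0.639). With each pellet library paired with the cells of its substrate, a fit added after the data were seen, this gene was not called (log2 difference 4.08, SE 0.45, limma, adjusted p = 0.0726) and 2 other genes were. Plastic is 1 library per stage, and no gene was called for this change of difference with median-of-ratios scaling, with a variance prior that ignores expression level, or without the ASC, the DF or the USC libraries; 300 genes were called without the SDSC libraries.

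Each dECM library was also set against the plastic library of its stage. With 1 library per group these differences have no replicate check, so they are described by the number of genes that differ by at least 1 on the log2(RPKM + 1) scale. In cells, ASC dECM was higher than plastic in 593 genes and lower in 570. DF dECM was higher in 545 and lower in 447, and USC dECM was higher in 432 and lower in 498. SDSC dECM lay closest to plastic, higher in 167 genes and lower in 297. In pellets, SDSC dECM differed from plastic in the most genes, 327 higher and 361 lower, and USC dECM in the fewest, 97 higher and 55 lower. DF dECM (189 and 104) and ASC dECM (181 and 95) lay between them, and their order turned with median-of-ratios scaling (271 genes for DF, 295 for ASC) and on the root-mean-square log2 difference from plastic (0.372 for DF, 0.396 for ASC). Simulated counting error alone gave from 26 to 47 such genes. ASC dECM and DF dECM cells were closest to each other among the pairs of cell libraries, with a root-mean-square log2 difference of 0.256 over all tested genes, against 0.694 between ASC dECM and plastic cells. In pellets the plastic and USC dECM libraries differed by 0.316 on that measure and the plastic and SDSC dECM libraries by 0.536. Counting error alone gave from 0.150 to 0.175.

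A library that lies above or below each of the other 4 libraries of its stage by at least 1 on the log2 scale was counted gene by gene. In cells, plastic stood apart in 250 genes, above the 4 dECMs in 155 and below them in 95. The counts in cells for the others were 22 genes for USC dECM, 12 for ASC dECM, 12 for DF dECM and 5 for SDSC dECM. In pellets, plastic stood apart in 37 genes (6 above, 31 below), while SDSC dECM stood apart in 120 genes (44 above, 76 below). DF dECM pellets stood apart in 25 genes, USC dECM pellets in 8 and ASC dECM pellets in 7. Simulated counting error alone gave from 1 to 5 genes. In the limma fit of the 10 libraries, each substrate in turn was set against the other 4 of its stage: plastic gave 221 calls in cells, SDSC dECM gave 23 in pellets (12 higher, 11 lower), and every other substrate and stage gave 0. These fits set 1 library against 4 and use the same libraries as the counts of genes. They have no replicate behind the single library and are no separate evidence that it stands apart. A library that stands apart is also among the other 4 when another substrate is singled out. Its difference then enters the error and lowers the count of that fit.

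**Figure D3:**
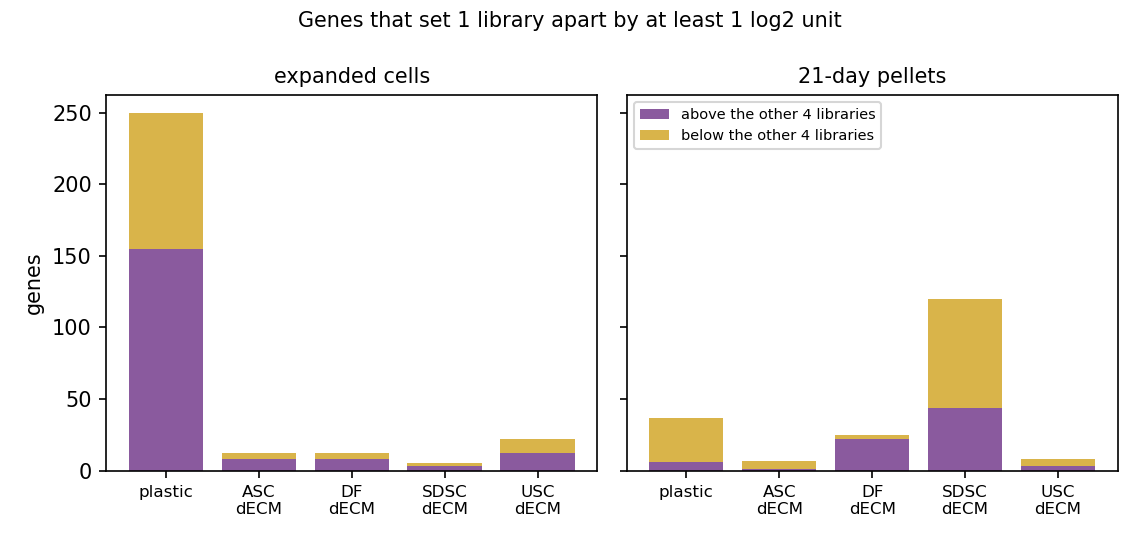
Number of genes in which 1 library lay above or below each of the other 4 libraries of its stage by at least 1 on the log2(RPKM + 1) scale, for the 5 substrates in cells and in pellets, with 1 library per bar. Plastic has the tallest bar in cells (250 genes) and SDSC dECM in pellets (120 genes).

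The matrix of urine stem cells is the one named in the series title, and its libraries were compared with those of the other 3 dECMs over both stages. No gene was called by limma, and 231 genes (1.89% of those tested) had an unadjusted p under 0.05. That is fewer than the share of 0.05 that chance alone gives. The error of this fit holds the spread among the other 3 dECMs and any stage difference that varies between classes. The lack of calls therefore does not show that USC dECM acts like the other dECMs. limma-voom on the recovered reads also called 0, as did the fits within cells and within pellets. In simulated data on the same 12244 genes, this comparison recovered 24% of the genes changed 1.5-fold, 66% of those changed 2-fold and 94% of those changed 4-fold. Each change was put into both USC libraries alike, with independent noise. A change in cells only or in pellets only was not simulated, so these shares do not cover it. Cells on USC dECM differed from plastic cells in 930 genes by at least 1 on the log2 scale. After pellet culture the USC dECM and plastic libraries differed in 152 genes, fewer than any other dECM library did.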

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

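Among the tests in this part, the other splits, the scaling test, the test for human RNA and the comparison of each substrate with the other 4 were chosen after the results were seen; the split of carry-over into higher and lower genes and its amount were chosen later still, and those of depth, gene length, carry-over over all 120 genes and abundant genes were set before their results. Dixon's test for a value far from the others was applied to 26 sets of 4 or 5 libraries or substrates, and 2 were found, where chance gives about 1 in 20.

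The plastic cell library stood apart from the others of its stage, in 250 genes against 5 to 22 for the 4 dECM cell libraries. With all libraries thinned to the same number of reads, 252 genes set it apart, 233 of them among the 250, and with a gene length trend removed from each library 249 did, 230 of them among the 250, which argues against depth and length bias. Human RNA left in the matrix could only raise genes on dECM, and so cannot account for the 155 genes that lay higher on plastic than on each dECM, as the median of all genes was lower by at most 0.07 on the log2 scale; for the 95 genes lower on plastic it cannot be told apart from a response of the rabbit cells without the reads. A real difference between plastic and dECM stays open, as does any handling difference of this single library, and neither was tested. The count needs a gap from every other library, so it stays low where libraries are alike. ASC and DF dECM cells differed from each other by at least 1 in 85 genes, which holds down the count of both. Each of the 5 substrates was also set against the other 4 in cells, and plastic gave the most calls. Where a dECM was singled out, the plastic library was among the other 4. Its difference then entered the error of that fit, which lowers the count. This comparison therefore cannot decide, and 5 splits are too few for a share under 0.05.

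The SDSC dECM pellet library stood apart from the others of its stage, in 120 genes against 7 to 37 for the other 4 pellet libraries. With all libraries thinned to equal reads 131 genes set it apart, 113 of them among the 120, and with the length trend removed 114 did, 102 of them among the 120, which argues against depth and length bias. Carry-over of undifferentiated SDSC dECM cells would place at least 90% of the genes between the other pellets and the SDSC dECM cells, and 60.8% of the 120 lay there, 47.7% of the 44 higher genes and 68.4% of the 76 lower ones. Under 70% had been set to count against it, and 60.8% met that rule (Wilson 95% interval 51.9% to 69.1%). A margin added after these results also counts in genes outside by less than 0.5 on the log2 scale. With it the share is 70.8% of all, 59.1% of the higher genes (upper end of the Wilson 95% interval 72.3%) and 77.6% of the lower ones. The rule set before thus argues against carry-over as the source of all 120 genes, but with the margin carry-over stays open. Even with the margin, 18 of the 44 higher genes and 17 of the 76 lower ones lay outside, where a mixture alone does not reach. For the 76 lower genes the amount was also compared, and each of the 52 that lay between needs at least 64.4% of such cells. That need is high by the choice of genes, which lie at least 1 below each other pellet on the log2 scale. The 144 genes abundant in cells, which fell in the other 4 substrates, put the share of such cells at a median of 3.97% with an upper quartile of 8.82%. The 228 genes that rose in the other 4 put it at a median of 39.2%, with quartiles of -14.4% and 60.3%. Taken alone, the fallen genes go against so large a share. The risen genes give a higher and wide one, so the amount does not decide on carry-over for the lower genes. A response to SDSC dECM and an event in this pellet or library both stay open as untested, since there is 1 library.

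Genes higher in pellets outnumbered those lower, 4626 to 2283. Scaled to the reads outside the 197 genes that were among the 100 most read in any library, the median change of all genes was 0.14 instead of 0.18, which kept 75.9% of it and argues against these abundant genes as the whole cause. With median-of-ratios scaling the share of higher genes was 51.4%, but that scaling centres the ratios, so a general rise in pellets and an effect of the scaling cannot be told apart without a spike-in or a measure of RNA per cell. The split into pellets and cells was also set against other splits of the 10 libraries into 5 and 5. Of 100 splits, 1, the real one, gave as many as 6909 genes, and the highest other gave 38. Every other split leaves the stage difference in the error of its fit, which lowers its count. Of the 12 splits drawn that part every substrate's pair, like the real one, the highest other gave 0. These 12 are too few for a share under 0.05.

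ENSOCUG00000011482 was the only gene called for a difference between stages in dECM minus plastic, 4.08 on the log2 scale (limma, adjusted p = 0.0362), with 1 plastic library per stage; with each pellet library paired with the cells of its substrate, a fit added after the data were seen, 2 other genes were called and this gene was not (limma, adjusted p = 0.0726). Its difference in pellets alone was not called (limma, adjusted p = 0.639), and no gene was called with median-of-ratios scaling, with a variance prior without trend, or without the ASC, the DF or the USC libraries.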

How the results depend on the processing

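Limma-voom, the paired fit for pellets minus cells and the fits without the SDSC dECM pellet library were chosen after the data were seen. For pellets against cells, the counts stayed within 1.5 times under all alternatives except a required log2 change of at least 1, which left 1107 higher and 752 lower genes; without the substrate term as a pairing block there were 4795 and 2394, and without each substrate in turn from 3695 to 4357 higher and from 1857 to 2275 lower. No gene list was tested, because no identifier could be named, so the lists' alternatives, such as an estimated correlation, were not run. The cause of the changes that follow was not tested, except where fewer libraries or genes enter by construction.

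For dECM against plastic in cells, the counts were 24 higher and 31 lower with a pseudocount of 0.1 RPKM, 31 and 280 with no filter, and 65 lower with a minimum mean of 5 RPKM. They were 0 and 0 in the cell libraries alone, and from 0 (without ASC or without USC) to 566 and from 0 to 697 (without SDSC) when a dECM was left out. Without DF there were 21 and 114. In pellets, no filter gave 104 genes and all other alternatives 0. For pellets minus cells, where 1 gene was called, no filter gave 147, median-of-ratios scaling 0, the prior without trend 0, limma-voom 4, the substrate as a pairing block 2 (not the same gene) and leaving out the SDSC dECM pellet library 5; leaving out each dECM gave from 0 to 300 (without SDSC). For USC against other dECMs, no filter gave 2 and all others 0.

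Genes that differ from plastic by at least 1 numbered, with a pseudocount of 0.1 RPKM, 785 for SDSC dECM in cells, and 535 (ASC), 557 (DF), 1073 (SDSC) and 360 (USC) in pellets. With a minimum mean of 5 RPKM they numbered 770 (ASC), 246 (SDSC) and 607 (USC) in cells, and 160 (ASC), 167 (DF) and 77 (USC) in pellets. The smaller counts follow from fewer genes tested.

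Genes that set a library apart, in the order plastic, ASC, DF, SDSC and USC, numbered 389, 53, 36, 52 and 61 in cells and 94, 44, 55, 202 and 31 in pellets with a pseudocount of 0.1 RPKM. At 1.5-fold they numbered 659, 91, 67, 83 and 115 in cells and 170, 68, 105, 562 and 40 in pellets. With a minimum mean of 5 RPKM they numbered 151, 4, 4, 1 and 13 in cells, and 3 for ASC and 3 for USC in pellets. Median-of-ratios scaling gave 8 for SDSC in cells. Plastic in cells and SDSC dECM in pellets had the highest count of their stage in each of these settings. Depth limits low genes: at 1 to 2 RPKM counting error alone had a coefficient of variation of 16.9%.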

Other observations

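The tests in this part, and the cuts used with them, were chosen after related results had been seen.

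Differences between dECM and plastic in the expanded cells were followed into the pellets. The 2 differences come from separate libraries, but the choice of genes does not. The spread behind the calls in cells was estimated over the dECM libraries of both stages, so dECM pellets entered that choice. A hypothesis was that the matrix leaves a lasting mark. Of the 221 genes called in cells, 104 (47.1%) had the same sign of dECM minus plastic in pellets, where a lasting difference had been set at over 75%. The 54 genes higher on dECM in cells had a median log2 difference of 1.89 there and -0.01 in pellets, and the 167 lower genes had medians of -1.61 and 0.01. Against 10000 random lists matched on mean expression, whose medians in pellets lay mostly below 0, the higher genes lay above 98.8% of lists, the direction seen in cells, and the lower genes above 99.9%, the opposite direction. For these genes as a set the data argue against a lasting difference of that size at 21 days, although single genes may have kept one, since the test was on the set.

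Another hypothesis was that dECM moves the expanded cells towards the pellet state. Genes that rose or fell in pellets of the other 3 dECMs gave an answer away from that state for each dECM: in ASC dECM minus plastic cells, for example, the 1084 risen genes had a median of -0.16 and the 762 fallen genes a median of 0.25. Genes taken from the plastic pair gave the opposite: the 1502 risen genes had a median of 0.12 and the 903 fallen genes a median of -0.40 in the same comparison. The direction therefore follows the choice of genes, because any dECM effect on cells enters the stage change of the dECM pairs, and chance or a plastic effect enters that of the plastic pair. On 0 of the 4 dECMs did both choices give an answer away from the pellet state, and none gave an answer towards it with both, so whether dECM moves cells along this axis cannot be told apart from the choice of genes.

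SDSC dECM was the matrix whose cells were closest to plastic cells and whose pellets were farthest from plastic pellets. Its cells differed from plastic in 464 genes by at least 1 on the log2 scale, against 930 to 1163 for the other 3 dECMs, and its pellets in 688 genes, against 152 to 293. Its change from cells to pellets was also the smallest, with a root-mean-square log2 change of 0.846 against 0.941 to 1.02 for the other substrates, and a slope of 0.802 on the mean change of the other 4. Plastic had the next lowest slope, 0.836. The values for SDSC dECM come from 1 cell library and 1 pellet library, so they are not separate evidence about the matrix. That pellet library is the one flagged above as standing apart.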
